A study of Drosophila melanogaster with 159 samples.

How the data were processed

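The deposited table holds log2 ratios of sample to reference RNA for 12588 probes on 159 arrays, a unit read from its values, which take both signs and stop at 16.61. Per the labels' protocols, embryos came from egg lays of 1 h, larvae were timed from hatching, pupae from the white prepupa and adults from eclosion, and adults were sorted by sex after freezing. Poly(A)+ RNA was extracted and the arrays were read on a GenePix scanner, per the labels' protocols. Background correction, spot filtering and the normalization behind the deposited log2 ratios are not given in the sources used here, so their scale and centring before deposit stay unknown. The labels give the ratio as red over green on all 159 arrays. The scan comments of 13 arrays name the sample as the red dye, none names it otherwise, and the channel label of every array calls the other RNA the reference. The direction of sample over reference was therefore stated for 13 arrays and taken as likely for the rest. The lowest correlation between any 2 arrays was -0.28, and 0 pairs lay under -0.3. Array medians of the log2 ratios ranged from -0.78 to 0.77, and 32.1 to 46.6% of the probes had no value on an array (median 37.1%).

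Probes were named from the platform annotation, updated through gene identifiers in a reference gene table of the Release 6 assembly, which held the gene of 4089 of the probes with a name and lacked that of 48. A single gene was named for 4137 probes, several genes for 159 and none for 8292, and no gene was named from a probe with several. The named probes covered 3046 genes. Where a gene had several probes, the one with the most values over all arrays was read, and other probes were mentioned where they differed in sign or call. Files name no genome build, so no coordinates are given. The genes RpL32 and Act5C, chosen as widely expressed controls, and tud and Acp26Aa had no probe with a single name, and Yp1 had only a probe with several.

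Groups and times were taken from the array titles, and the title was kept for the 6 arrays whose scan comment disagrees with it. Each array was centred on its median. The 252 values at the upper limit (log2 above 16) were treated as missing, a choice made after the data were examined. The tests, the arrays in each fit, the gene lists, the rule for named genes and the alternatives, apart from those named below as added, were fixed before the data were examined. Tests used limma (version 3.58.1, in R 4.3.3 with the data.table package, 1.17.8), with lmFit and moderated variances, Benjamini-Hochberg adjustment, two-sided tests and a threshold of 0.05 on the adjusted p. A probe was tested where at least 80% of the arrays of the fit had a value. The slide numbers take 2 forms, read as 2 print series and called slide set A (57 arrays) and slide set B (102 arrays), and the set was a term in every model. The title of embryo 6-7 h replicate 2 lacks the letters of the second form, and the array was placed in slide set B. Comparisons between windows of time used only the arrays of those windows. Sexed larvae were compared in a fit to all 24 larval arrays, and tudor flies in a fit to all 40 adult arrays with a mean for each sex and age and a tudor effect for each sex. The comparison of adult sexes and the ageing slopes used the 32 wild-type adult arrays, with age as a factor or as days within each sex, and flies of 0 to 24 h were set at 0.5 d. Slopes are given per 10 days.

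Gene lists were tested with limma's cameraPR at a preset correlation between genes of 0.01, again with a correlation estimated from the residuals, and adjusted over the lists of a comparison. A list needed at least 3 measured members, with 1 probe per gene. Named genes were the 5 largest increases and 5 largest decreases among probes that passed, with a single gene name, and up to 4 members of each list past the test, those with the smallest adjusted p, together with the control genes. This rule named 166 genes. The muscle structure list, fixed in advance, also holds Sod3, a superoxide dismutase gene. It was kept, and a test without it was added after the data were examined. Acp36DE was given in tudor males as a gene the rule named for the adult sexes.

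Alternatives were the values without centring, quantile normalization, other filters on missing values, probes of a gene averaged, no slide set term, the replicate number or the slide as a block, each slide set alone, means of every time point, other scales or ranges of age, arrays left out for disagreeing labels and each array left out in turn. After the data were examined, fits were added without the 4 arrays that resembled no other, without the 9 replicate 1 arrays at 20 to 80 h of metamorphosis, without larvae of 105 h, the last larval time point, with the values at the upper limit kept, with Sod3 left out of the muscle list, without a 42 h pupal array, with each age of the tudor flies alone, and with tudor fitted only to adult arrays of 0 to 24 h and 5 d. The 4 arrays that resembled no other were compared only with arrays outside the 4, and likeness among them was not tested. Rows of each array were checked against its neighbours in time in stretches of 40 probes. The shift of 120 rows used there was found after the data were examined. The fits were tested on simulated data with 200 changed probes per comparison. At a log2 change of 2, they recovered 90% in the early embryo, 97% in the late embryo, larva, pupa and late pupa, 94% in the prepupa, 87% between larval sexes, and 100% between adult sexes and for the 3 ageing comparisons. For tudor they recovered 94% in females, 91% in males and 80% for the difference. At a log2 change of 1 they recovered 69% in the early embryo, 72% in the late embryo, 67% in the larva, 61% in the prepupa, 67% in the pupa, 71% in the late pupa, 34% between larval sexes and 96% between adult sexes. For tudor the shares were 44% in each sex and 22% for the difference, and for ageing 99% in females, 100% in males and 93% for the difference. In the ageing comparisons both sizes are changes per 10 days. Of the called slopes, 16 of 597 in females, 19 of 744 in males and 2 of 94 for the difference reached 1 per 10 days. Noise was drawn independently for each array, so deviations shared by arrays on a slide were not imitated. False calls numbered 3 to 12 per comparison, each run on its own tested probes, from 6615 to 7003. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.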

Results

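RNA levels were followed through the life cycle of the fruit fly Drosophila melanogaster on cDNA arrays, each of which set the RNA of 1 sample against a common reference RNA. The arrays fell into 80 groups, of which 79 held 2 arrays and the time point at 0 h of metamorphosis held 1. Embryos were covered by 60 arrays from 30 overlapping collections of 1 h, larvae by 24 arrays in 12 groups, metamorphosis by 35 arrays at 18 times after the white prepupa, and wild-type adults by 32 arrays in 16 groups by sex and age. A further 8 adult arrays in 4 groups carried flies that the titles call tudor, after the gene needed for germ plasm assembly and germ cell formation. The titles do not say whether these flies or their mothers lacked the gene. The growth text of the same arrays names the wild-type strain. Each array gave between 6722 and 8546 values for 12588 probes, and the median log2 ratio of an array lay between -0.78 and 0.77. Positive values mean more RNA in the sample than in the reference, a direction stated for part of the arrays and taken for the rest. The labels do not say whether replicate arrays came from separate collections of animals, so p-values measure the spread between these arrays, which may be technical. The small number of arrays per group limits the precision of each value.

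Replicate arrays resembled each other across probes to different degrees by stage, although probes are not independent measurements. The arrays lay on slides of 2 numbering forms, called slide set A (57 arrays) and slide set B (102 arrays) here. Across the sets, the median correlation of replicate pairs was 0.869 over 23 embryo pairs, 0.860 over 8 larval pairs, 0.828 over 10 adult pairs and 0.428 over 16 metamorphosis pairs. The 4 arrays embryo 2-3 h replicate 1, embryo 4-5 h replicate 1, metamorphosis 12 h replicate 1 and metamorphosis 16 h replicate 1 reached at most 0.344 with any array of another group outside these 4. At 9 times from 20 to 80 h of metamorphosis, replicate 1 and replicate 2 correlated with a median of 0.418, against 0.822 and 0.803 between neighbouring times within each set of 9 arrays.

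Single genes traced different courses through the life cycle. Transcripts of up, which encodes muscle troponin T, stood at -4.41 ± 2.37 (SD, n = 8) in embryos of 4 to 6.5 h and at 2.32 ± 0.53 (SD, n = 8) in embryos of 20 to 24 h. Without embryo 4-5 h replicate 1, the first mean was -5.24 ± 0.24 (SD, n = 7). They stood at -4.81 ± 0.45 (SD, n = 7) at 0 to 6 h of metamorphosis and at 2.37 ± 0.52 (SD, n = 6) at 72 to 96 h. PCNA, the sliding clamp of DNA replication, stood at 2.68 ± 0.51 (SD, n = 8) and -1.24 ± 0.22 (SD, n = 8) in the same embryo windows, at 1.96 ± 0.56 (SD, n = 16) in adult females and at -2.17 ± 0.45 (SD, n = 16) in adult males. By limma's moderated F test, 6679 of 6891 tested probes (96.9%) differed among the 80 groups at an adjusted p under 0.05. Within embryos, 5634 of 6960 probes changed over the 30 collections. Within metamorphosis, 1286 of 6861 probes changed over the 18 times, and 2282 had an unadjusted p under 0.05. Without the 9 replicate 1 arrays at 20 to 80 h the metamorphosis count was 481, and without the 4 arrays that resembled no other it was 1810.

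**Figure D1:**
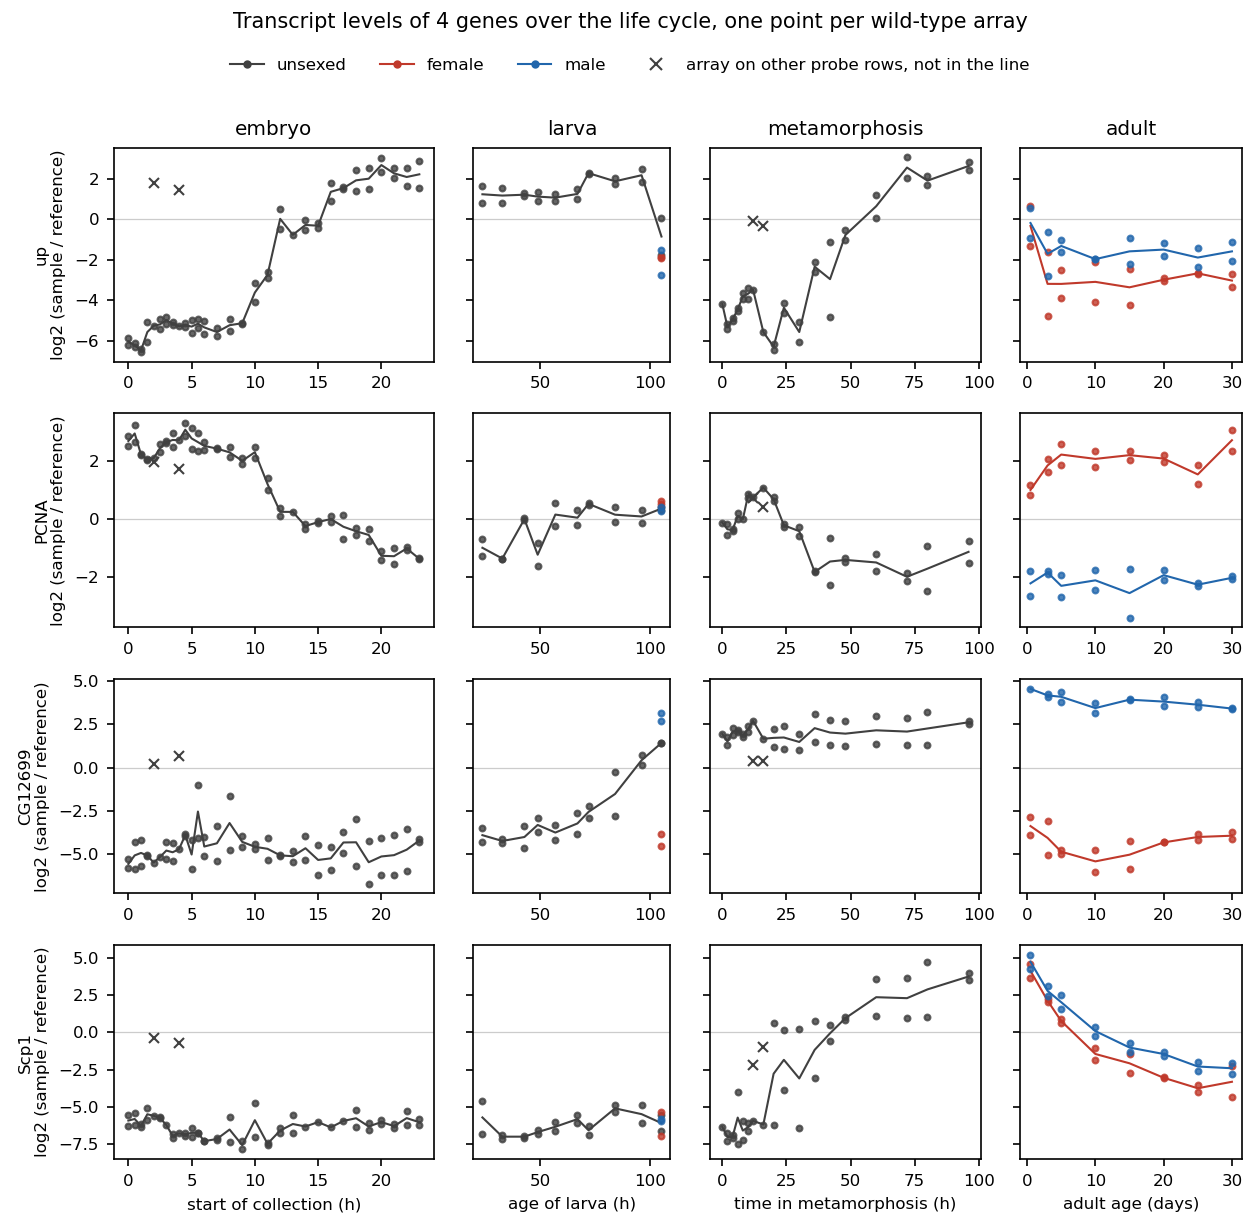
Log2 ratio of sample to reference (y axis) of up, PCNA, CG12699 and Scp1 against time within each stage (x axis, hours or days). There is 1 point for each wild-type array, with crosses for the 4 arrays that resembled no array outside these 4. The genes were picked for the picture after their values had been seen. For up, embryos of 4 to 6.5 h stand at -4.41 ± 2.37 (SD, n = 8), or -5.24 ± 0.24 (SD, n = 7) without embryo 4-5 h replicate 1, and those of 20 to 24 h at 2.32 ± 0.53 (SD, n = 8).

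Gene groups were compared through 20 gene lists, of which 18 had at least 3 measured members. The lists of salivary gland glue genes and of yolk and eggshell genes had 0 probes with a single gene name. Over 14 comparisons, 240 list tests gave 45 results at an adjusted p under 0.05, of which 17 also held with an estimated correlation between genes and 28 did not. The muscle structure list also holds Sod3, a superoxide dismutase gene, noticed after the data were examined. Without it the list passed in the same 6 comparisons. In the 45 results the median, the mean and the test had the same sign. In 22 of them that slide set A alone could test and in all 45 with slide set B alone, the list median kept its sign. Of 216 results of genes picked by the naming rule that compare 2 groups and passed the test, 204 had every array of the second group on the same side of the mean of the first, 10 had all arrays but 1, and 2 had fewer. The genes were picked and tested on the same arrays, so a high share follows largely from the selection.

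**Figure D2:**
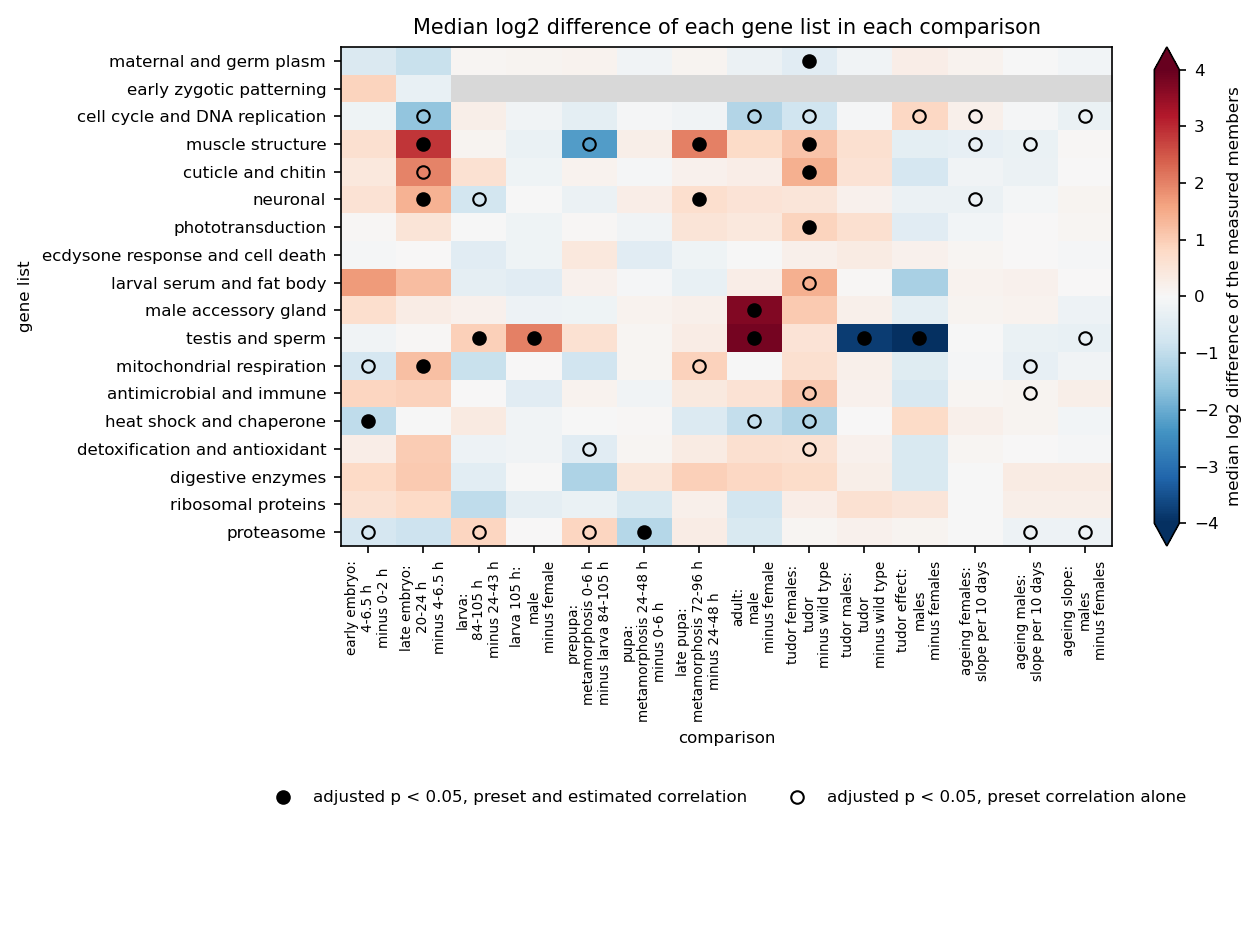
Median log2 difference of the measured members of 18 gene lists (rows) in 14 comparisons (columns), with ageing given as log2 change per 10 days. Filled dots mark the 17 results past the test with both the preset and the estimated correlation, open dots those past it with the preset correlation alone, and grey fields lists with fewer than 3 members. The lowest median is -4.34, for testis and sperm genes in the difference of the tudor effects between the sexes.

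In the first hours of development, embryos of 4 to 6.5 h were compared with those of 0 to 2 h, before and after the onset of zygotic transcription. ImpL2, which encodes a secreted insulin-binding protein, rose by 4.64 ± 0.38 (SE) on the log2 scale, from -2.75 ± 0.56 (SD, n = 6) to 1.90 ± 0.86 (SD, n = 8; adjusted p = 2.65e-07). The Na,K-ATPase subunit gene nrv2 rose by 4.43 ± 0.22 (SE), CG2145 by 4.28 ± 0.28 (SE), CG5888 by 4.15 ± 0.21 (SE) and the lysine catabolism gene LKRSDH by 4.01 ± 0.48 (SE). Transcripts of mtrm, an inhibitor of Polo kinase in female meiosis, fell by 4.16 ± 0.45 (SE), from 3.77 ± 0.42 (SD, n = 6) to -0.34 ± 1.18 (SD, n = 8; adjusted p = 3.95e-06). CNBP fell by 3.80 ± 0.49 (SE), as did the isocitrate dehydrogenase gene Idh (-3.79 ± 0.21, SE), the prefoldin-like uri (-3.76 ± 0.42, SE) and CG6180 (-3.72 ± 0.20, SE). Of 7 heat shock and chaperone genes, 4 fell and 3 passed neither way (median -1.01, adjusted p = 0.0139; 4 adjusted over the list alone), among them Hsp27 (-2.49 ± 0.20, SE) and the chaperonin subunit gene CCT7 (-1.53 ± 0.14, SE). Of 10 proteasome genes, 8 fell, 8 also adjusted over the list alone, with Prosalpha1 at -1.91 ± 0.17 (SE) and the list median at -0.68 (adjusted p = 0.0139). The proteasome call did not hold with an estimated correlation (adjusted p = 0.348) or in slide set B alone (adjusted p = 0.0549). In slide set A alone the proteasome median was -1.17 and the heat shock median -1.64. With only probes measured on every array the heat shock median was -1.53. Of 8 genes of mitochondrial respiration, 5 fell and 1 rose, 5 and 1 also adjusted over the list alone (median -0.68, adjusted p = 0.0139). This call was lost (adjusted p = 0.0574 with an estimated correlation). The 3 genes of early zygotic patterning had a median of 0.88 with 2 higher, 2 also adjusted over the list alone, and the list did not pass (adjusted p = 0.477). By limma, 3698 of 6996 probes passed, 2253 higher and 1445 lower. Of these, 1053 and 683 differed at least 2-fold. Without centring, which moved the median of all probes by -0.17, 1686 were higher and 1723 lower, and with quantile normalization, which moved it by -0.15, 1667 and 1647. Slide set B alone gave 4529 probes, and slide set A, which holds embryo 4-5 h replicate 1, gave 0 by limma with 1379 at an unadjusted p under 0.05. There CG2145 and LKRSDH could not be tested, and the calls of the other genes named in this comparison ended, with ImpL2 at 3.88 and mtrm at -6.02. Without the arrays that resembled no other, 4464 probes passed.

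From 4 to 6.5 h to 20 to 24 h, most measured muscle and neuronal genes rose. The largest increases among named genes were those of fau (8.95 ± 0.27, SE), of Ssk, a smooth septate junction gene (7.89 ± 0.25, SE), of Zasp66, which encodes a Z-disc protein (6.94 ± 0.28, SE), of HisT (6.85 ± 0.60, SE) and of up (6.48 ± 0.79, SE). Ssk went from -4.60 ± 0.70 (SD, n = 8) to 3.23 ± 0.15 (SD, n = 8; adjusted p = 3e-13). Of 16 muscle structure genes, 12 rose and 4 passed neither way (median 2.86, adjusted p = 1.48e-07; 12 adjusted over the list alone), among them paramyosin Prm (4.97 ± 0.17, SE), myofilin Mf (4.83 ± 0.24, SE) and obscurin Obsc (3.81 ± 0.14, SE). Of 19 neuronal genes, 13 rose and 2 fell, 13 and 2 also adjusted over the list alone (median 1.39, adjusted p = 0.00478), with the calcium-activated potassium channel gene slo at 3.67 ± 0.13 (SE). Of 8 genes of mitochondrial respiration, 7 rose and 1 fell, 7 and 1 also adjusted over the list alone (median 1.19, adjusted p = 0.00607), and Idh rose by 4.78 ± 0.20 (SE). All 12 measured cuticle and chitin genes rose, 12 also adjusted over the list alone (median 2.00, adjusted p = 0.00431), with the chitinase-like Idgf1 at 5.28 ± 0.35 (SE) and the chitinase gene Cht7 at 4.54 ± 0.49 (SE). That list call was lost with an estimated correlation (adjusted p = 0.149). The adhesion gene Ama fell by 4.71 ± 0.40 (SE), as did the Notch fucosyltransferase gene O-fut1 (-4.34 ± 0.14, SE), the Wingless pathway gene Axn (-4.21 ± 0.47, SE), CG14464 (-4.12 ± 0.12, SE) and the augmin subunit gene dgt3 (-4.09 ± 0.20, SE). Of 15 cell cycle and DNA replication genes, 11 fell, 11 also adjusted over the list alone (median -1.56, adjusted p = 4.35e-04), among them PCNA (-3.86 ± 0.20, SE) and Aurora B kinase aurB (-3.60 ± 0.31, SE). The cell cycle call was lost with an estimated correlation (adjusted p = 0.233). By limma, 4886 of 6995 probes passed, 2452 higher and 2434 lower. Of these, 1609 and 1480 differed at least 2-fold. Leaving out centring moved the median of all probes by -0.23. Slide set A alone gave 3066 probes, with a muscle list median of 1.15, and ended the call of up, at 3.76. Slide set B gave 5799. Without the arrays that resembled no other, 5307 probes passed and up rose by 7.76.

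Larval growth was read between larvae of 24 to 43 h and those of 84 h and later. CG12699 rose by 4.16 ± 0.54 (SE), from -4.06 ± 0.49 (SD, n = 6) to 0.10 ± 1.57 (SD, n = 6; adjusted p = 1.49e-04), CG10570 by 3.61 ± 0.35 (SE), CG10962 by 3.29 ± 0.24 (SE), CG10252 by 3.19 ± 0.35 (SE) and CG7906 by 3.17 ± 0.87 (SE). Of 7 testis and sperm genes, 5 rose, 5 also adjusted over the list alone (median 0.96, adjusted p = 0.00284), among them exu, needed for RNA localisation in the egg and for sperm development (1.92 ± 0.29, SE), and the axonemal Tektin-A (0.96 ± 0.16, SE). The calmodulin-binding gene igl fell by 4.05 ± 0.20 (SE), from 1.93 ± 0.18 (SD, n = 6) to -2.12 ± 0.50 (SD, n = 6; adjusted p = 5.57e-08), as did CG1774 (-3.91 ± 0.29, SE), the carbonic anhydrase gene CAH2 (-3.16 ± 0.25, SE), Qsox2 (-2.71 ± 0.38, SE) and slo (-2.64 ± 0.23, SE). Of 18 neuronal genes, 12 fell, with 13 lower and 1 higher adjusted over the list alone (median -0.74, adjusted p = 1.24e-04), among them the synaptic vesicle gene nSyb (-1.13 ± 0.20, SE). The neuronal call was lost with an estimated correlation (adjusted p = 0.203). Of 9 proteasome genes, 7 rose, 7 also adjusted over the list alone (median 0.87, adjusted p = 0.00756), with Rpt2 at 1.41 ± 0.22 (SE), and this call did not hold either (adjusted p = 0.577 with an estimated correlation). The 3 ribosomal protein genes all fell, 3 also adjusted over the list alone (median -1.03), but the list did not pass (adjusted p = 0.155). By limma, 2063 of 6645 probes passed, 921 higher and 1142 lower. Of these, 310 and 540 differed at least 2-fold. Without centring, which moved the median of all probes by -0.15, 451 were higher and 1288 lower. Slide set B alone gave 1706 probes and slide set A 70, where the calls of CG12699, CG10252, exu, nSyb and Rpt2 ended and CG7906 stood at -0.09. The testis list (median 0.74, adjusted p = 0.0582) and the proteasome list (median 0.63, adjusted p = 0.0944) did not pass there either. With the means of every larval time point in the model, 3127 probes passed.

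Larvae of the last time point were also sexed, and the sexes differed in 240 of 6609 probes, 236 of them higher in males and 4 lower. CG12699 was higher in males by 7.11 ± 0.55 (SE), at -4.19 ± 0.50 (SD, n = 2) in females and 2.92 ± 0.34 (SD, n = 2) in males (adjusted p = 3.66e-07). The gene vrs was higher by 5.89 ± 0.39 (SE), CG10252 by 5.48 ± 0.42 (SE), CG8701 by 5.29 ± 0.40 (SE) and CG1324 by 5.16 ± 0.43 (SE). Of 7 testis and sperm genes, 6 were higher in males, 6 also adjusted over the list alone (median 2.01, adjusted p = 9.37e-09), among them the testis chaperonin gene Hsp60B (2.82 ± 0.47, SE), hmw (2.14 ± 0.31, SE), Tektin-A (2.01 ± 0.29, SE) and the phosphoglycerate mutase gene Pglym87 (1.86 ± 0.33, SE). CG10962 was the 1 gene with a single name that was lower in males (-1.44 ± 0.32, SE), at 2.85 ± 0.78 (SD, n = 2) in females and 1.41 ± 0.08 (SD, n = 2) in males. Without the female replicate 2 array it stood at -0.89 and did not pass, nor did it pass without a slide set term (adjusted p = 0.0671) or without centring (adjusted p = 0.0955). These counts are from limma fitted to all 24 larval arrays, without pairing. Female and male arrays of the same replicate number lay on the same slide, and their deviations correlated at 0.72. With the slide as a random block 447 probes passed. All 4 sexed arrays lay in slide set B, which alone gave 146 probes and ended the calls of CG10962 and Hsp60B.

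The onset of metamorphosis was read between larvae of 84 h and later and prepupae of 0 to 6 h. Of 15 muscle structure genes, 10 fell and 5 passed neither way, with 12 lower and 1 higher adjusted over the list alone (median -2.24, adjusted p = 2.14e-07). The muscle call was lost with an estimated correlation (adjusted p = 0.126). Among its members up fell by 5.92 ± 0.55 (SE), from 1.07 ± 1.62 (SD, n = 6) to -4.81 ± 0.45 (SD, n = 7; adjusted p = 3.58e-06), as did Mf (-4.37 ± 0.24, SE) and Obsc (-3.01 ± 0.47, SE). The muscle kinase gene Strn-Mlck fell by 2.56 ± 0.33 (SE), which its other probe did not show. The glycosyltransferase gene Eogt fell by 7.08 ± 0.50 (SE), as did CG2691 (-6.38 ± 0.69, SE), CG10472 (-6.27 ± 0.85, SE) and the splicing kinase gene Prp4k (-5.90 ± 0.27, SE). CG32631 rose by 5.04 ± 0.63 (SE), from -1.96 ± 0.64 (SD, n = 6) to 3.14 ± 1.72 (SD, n = 7; adjusted p = 4.27e-05), CG4702 by 4.62 ± 0.86 (SE), CG7906 by 4.58 ± 1.03 (SE), the serpin gene Spn100A by 4.16 ± 0.51 (SE) and CG8420 by 3.55 ± 0.38 (SE). Of 41 detoxification and antioxidant genes, 15 fell and 1 rose, with 16 and 2 adjusted over the list alone (median -0.45, adjusted p = 0.00234), among them the cytochrome P450 genes Cyp4ac1 (-3.75 ± 0.38, SE), Cyp28a5 (-3.41 ± 0.41, SE) and Cyp4c3 (-3.07 ± 0.24, SE). The detoxification call was lost with an estimated correlation (adjusted p = 0.437), and the median was -0.07 without centring. Of 9 proteasome genes, 6 rose, 7 adjusted over the list alone (median 0.87, adjusted p = 0.0135), with the lid subunit gene Rpn5 at 1.30 ± 0.26 (SE). It did not hold (adjusted p = 0.437 with an estimated correlation). The 8 genes of ecdysone response and cell death (median 0.43; 2 higher, 1 lower, with 3 and 1 adjusted over the list alone) and the 4 digestive enzyme genes (median -1.25; 3 lower, 3 also adjusted over the list alone) did not pass as lists (adjusted p = 0.431 and 0.108). By limma, 2241 of 6661 probes passed, 1064 higher and 1177 lower. Of these, 480 and 695 differed at least 2-fold. Without centring, which moved the median of all probes by 0.37, 1993 were higher and 576 lower. Slide set A alone gave 1840 probes, with a detoxification median of -0.83. Slide set B gave 600, with a muscle median of -1.19, and there CG4702, CG7906 and Rpn5 were not called and the proteasome list did not pass. Without the last larval time point, 2744 probes passed.

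Between 0 to 6 h and 24 to 48 h of metamorphosis, most measured proteasome genes fell. Of 9 measured members, 7 fell, 7 also adjusted over the list alone (median -1.13, adjusted p = 7.92e-08). The list also passed with an estimated correlation (adjusted p = 3.92e-05). Rpt2 fell by 1.87 ± 0.20 (SE), from 1.47 ± 0.56 (SD, n = 7) to -0.47 ± 0.70 (SD, n = 10; adjusted p = 6.53e-06), as did Rpt5 (-1.40 ± 0.19, SE), Rpn5 (-1.21 ± 0.14, SE) and Prosalpha1 (-1.12 ± 0.16, SE). CG32631 fell by 5.17 ± 0.49 (SE), as did CG8329 (-4.78 ± 0.34, SE), CG7906 (-4.24 ± 0.85, SE), CG8929 (-3.78 ± 0.72, SE) and CG9021 (-3.73 ± 0.46, SE). Scp1, which encodes a sarcoplasmic calcium-binding protein, rose by 5.45 ± 0.89 (SE), from -6.58 ± 1.20 (SD, n = 7) to -1.04 ± 2.55 (SD, n = 10; adjusted p = 2.74e-04). The cuticle protein genes Cpr49Ae (3.89 ± 0.48, SE) and Cpr72Ea (3.87 ± 0.55, SE) rose as well, as did CG2691 (3.87 ± 0.61, SE) and Eogt (3.76 ± 0.68, SE). By limma, 2050 of 6787 probes passed, 1016 higher and 1034 lower. Of these, 344 and 386 differed at least 2-fold. The replicate 1 arrays of 24 to 48 h are among the 9 at 20 to 80 h that correlated with their partners at a median of only 0.418. A deviation they share may therefore enter the count of 2050. Without these 9 arrays, 715 probes passed, and Scp1 (3.43), Eogt (3.22) and CG8929 (-0.90) were not called. Slide set A alone, whose 24 to 48 h arrays are all among the 9, gave 2569 probes, where CG7906 was at -1.57 and not called. Slide set B, which leaves out the 9, gave 450 and ended the calls of Scp1, Eogt and CG8929. The means of every time point in the model gave 1278.

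Towards eclosion, most measured muscle and neuronal genes rose between 24 to 48 h and 72 to 96 h of metamorphosis. Flightin fln, of the thick filaments of flight muscle, rose by 7.17 ± 0.85 (SE), from -3.27 ± 2.42 (SD, n = 10) to 4.16 ± 0.77 (SD, n = 6; adjusted p = 8.79e-06), up by 5.46 ± 0.74 (SE), Mf by 4.53 ± 0.16 (SE) and alpha-actinin Actn by 3.02 ± 0.31 (SE). Of 16 muscle structure genes, 9 rose and 1 fell, 9 and 1 also adjusted over the list alone (median 2.01, adjusted p = 1.11e-09). The muscle median was 0.60 in slide set A alone and 1.11 with complete probes only. Of 19 neuronal genes, 12 rose and 1 fell, with 14 and 1 adjusted over the list alone (median 0.66, adjusted p = 4.77e-04), among them Ddc, of dopamine and serotonin synthesis (1.85 ± 0.18, SE), and the amyloid precursor-like Appl (1.27 ± 0.20, SE). Of 7 genes of mitochondrial respiration, 5 rose, 5 also adjusted over the list alone (median 0.92, adjusted p = 9.44e-04), with Idh3b at 2.89 ± 0.28 (SE) and the ATP synthase subunit gene ATPsynF at 2.69 ± 0.41 (SE). The mitochondrial call was lost with an estimated correlation (adjusted p = 0.0692) and in slide set A alone (median 0.41, adjusted p = 0.0544). In slide set B alone the mitochondrial median was 1.72 (limma's cameraPR, adjusted p = 3.29e-04). The 9 phototransduction genes (median 0.52; 3 higher, 3 also adjusted over the list alone) missed the threshold (adjusted p = 0.0646) and passed it with an estimated correlation (adjusted p = 0.0495). CG2691 rose by 4.35 ± 0.73 (SE) and CG11912 by 4.34 ± 0.30 (SE), while CG4702 fell by 3.73 ± 0.80 (SE), as did Cpr72Ea (-3.29 ± 0.63, SE), the small heat shock gene Hsp27 (-3.14 ± 0.40, SE), tpr (-2.35 ± 0.76, SE) and Spn100A (-2.30 ± 0.52, SE). Without the metamorphosis 96 h replicate 2 array, tpr stood at -1.98 and did not pass, nor without arrays of disagreeing labels (adjusted p = 0.0582), nor did Spn100A without a slide set term (-1.94, adjusted p = 0.148). By limma, 2333 of 6868 probes passed, 1267 higher and 1066 lower. Of these, 694 and 195 differed at least 2-fold. Slide set A alone gave 1835 probes, where CG4702 and tpr were not called, and slide set B, which leaves out the 9 replicate 1 arrays, gave 1662.

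Between the sexes of wild-type adults at 8 matched ages, most measured genes of the testis and accessory gland were higher in males. CG12699 was higher in males by 8.31 ± 0.17 (SE), at -4.39 ± 0.86 (SD, n = 16) in females and 3.83 ± 0.39 (SD, n = 15) in males (adjusted p = 4.96e-26). Acp36DE, which encodes a seminal fluid protein, was higher by 8.07 ± 0.21 (SE), CG8701 by 7.61 ± 0.25 (SE), CG10252 by 7.53 ± 0.17 (SE) and CG17377 by 7.46 ± 0.19 (SE). Of 7 testis and sperm genes, 6 were higher in males and 1 lower, 6 and 1 also adjusted over the list alone (median 3.82, adjusted p = 1.96e-04), among them Hsp60B (4.84 ± 0.26, SE) and Tektin-A (4.47 ± 0.15, SE). The testis median was 2.30 over the ages of 20, 25 and 30 d alone. All 3 male accessory gland genes were higher, 3 also adjusted over the list alone (median 3.71, adjusted p = 1.09e-04). The accessory gland median was 5.89 with no filter on missing values and 6.37 in slide set A alone. PCNA was lower in males (-4.12 ± 0.16, SE), at 1.96 ± 0.56 (SD, n = 16) in females and -2.17 ± 0.45 (SD, n = 16) in males (adjusted p = 9.05e-20). Lower in males were also the spermathecal protease gene Send1 (-4.11 ± 0.25, SE), mtrm (-4.10 ± 0.28, SE), Lpt, of a histone methyltransferase complex (-3.85 ± 0.20, SE), and CG14464 (-3.67 ± 0.15, SE). Of 16 cell cycle and DNA replication genes, 13 were lower in males and 1 higher, 13 and 1 also adjusted over the list alone (median -1.18, adjusted p = 1.96e-04), and this call was lost with an estimated correlation (adjusted p = 0.109). Of 7 heat shock and chaperone genes, 6 were lower in males and 1 higher, 6 and 1 also adjusted over the list alone (median -0.94, adjusted p = 0.0299), with CCT7 at -1.95 ± 0.10 (SE). The list call ended with an estimated correlation (adjusted p = 0.109), with quantile normalization (adjusted p = 0.0788) and in slide set A alone (adjusted p = 0.217). It ended as well with complete probes only (adjusted p = 0.141) and without a slide set term (adjusted p = 0.101). By limma, 5073 of 6860 probes passed, 2737 higher and 2336 lower in males. Of these, 1034 and 697 differed at least 2-fold. Without centring, which moved the median of all probes by -0.23, 2010 were higher and 2908 lower, and quantile normalization moved that median by -0.14. Slide set A alone gave 3502 probes and slide set B 5510.

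In tudor females, some maternal and germ plasm genes were lower than in wild-type females of 0 to 24 h and 5 d, and most measured muscle, cuticle and phototransduction genes were higher. The gene tud itself had no probe with a single gene name, so the titles could not be checked on it. Pendulin Pen, an importin alpha, was lower (-4.62 ± 0.37, SE), at 0.99 ± 0.32 (SD, n = 4) in wild-type and -3.56 ± 0.82 (SD, n = 4) in tudor females (adjusted p = 3.19e-09). Also lower were exu (-4.36 ± 0.38, SE), CG14464 (-4.18 ± 0.40, SE), the peroxidase gene Pxt (-4.02 ± 0.56, SE) and swa, needed to localise bicoid RNA (-3.95 ± 0.45, SE). Of 12 maternal and germ plasm genes, 4 were lower and 8 passed neither way (median -0.45, adjusted p = 0.00177; 4 adjusted over the list alone), with a median of -0.28 without adult female 5 d replicate 2 and -0.18 without a slide set term. Of 16 cell cycle and DNA replication genes, 9 were lower and 1 higher, 9 and 1 also adjusted over the list alone (median -0.79, adjusted p = 1.48e-04), with PCNA at -3.80 ± 0.43 (SE), and the call was lost with an estimated correlation (adjusted p = 0.0739). Higher in tudor females were CG6415 (3.00 ± 0.30, SE), Cyt-b5-r (2.95 ± 0.29, SE), CG12219 (2.86 ± 0.34, SE), Tdh (2.85 ± 0.45, SE) and the cathepsin gene CtsK2 (2.81 ± 0.30, SE). Of 16 muscle structure genes 10 were higher, 11 adjusted over the list alone (median 1.13), of 12 cuticle and chitin genes 9, 10 adjusted over the list alone (median 1.42), and of 9 phototransduction genes 6, 6 also adjusted over the list alone (median 0.88), each list at an adjusted p of 0.00177. Prm was higher by 1.62 ± 0.22 (SE), Idgf2 by 1.64 ± 0.24 (SE), the eye protein kinase C gene inaC by 1.75 ± 0.22 (SE) and the carotenoid oxygenase gene ninaB by 2.13 ± 0.26 (SE), while Strn-Mlck (2.08 ± 0.26, SE) differed from its other probe. Of 40 detoxification and antioxidant genes, 16 were higher and 1 lower, 16 and 1 also adjusted over the list alone (median 0.60, adjusted p = 0.00177), with Cyp9c1 at 2.54 ± 0.38 (SE). This call was lost (adjusted p = 0.0739 with an estimated correlation), also with complete probes only (adjusted p = 0.052), and the median was 0.37 without adult female 5 d replicate 2. Of 7 heat shock and chaperone genes, 4 were lower and 1 higher, 4 and 1 also adjusted over the list alone (median -1.20, adjusted p = 0.00256), with Hsp27 at -2.83 ± 0.43 (SE). It did not hold (adjusted p = 0.0739 with an estimated correlation), nor with complete probes only (adjusted p = 0.052). Without a slide set term the heat shock median was -0.21 (adjusted p = 0.0682). Of 8 antimicrobial and immune genes 5 were higher, 5 also adjusted over the list alone (median 1.09, adjusted p = 0.021), and all 3 genes of larval serum and fat body were higher, 3 also adjusted over the list alone (median 1.43, adjusted p = 0.0369). Both calls were lost with an estimated correlation (adjusted p = 0.128), and the fat body list also without the adult female 5 d replicate 1 array (adjusted p = 0.0608), without a slide set term (adjusted p = 0.155) and in slide set B alone (adjusted p = 0.053). The immune list did not pass with complete probes only (adjusted p = 0.0708). By limma, 2645 of 7003 probes passed, 1695 higher and 950 lower. Of these, 1053 and 516 differed at least 2-fold. Without centring, which moved the median of all probes by -0.16, 1126 were higher and 1080 lower, and with quantile normalization, which moved it by -0.18, 995 and 1025. All 8 tudor arrays lay in slide set B, which alone gave 2148 probes, and the arrays of 0 to 24 h alone gave 1229, where Tdh stood at 1.14 and was not called. There the maternal median was -0.21, and the immune and fat body lists did not pass (adjusted p = 0.102 and 0.189). With the tudor arrays of 5 d alone, the medians were 1.63 for phototransduction, 1.10 for detoxification and -1.28 for the cell cycle.

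In tudor males, testis and sperm genes were lower than in wild-type males of the same ages. CG12699 was lower (-7.92 ± 0.41, SE), at 4.24 ± 0.40 (SD, n = 3) in wild-type and -3.17 ± 0.39 (SD, n = 4) in tudor males (adjusted p = 1.8e-14). Also lower were CG10252 (-7.60 ± 0.36, SE), CG1324 (-7.27 ± 0.35, SE), CG8701 (-7.20 ± 0.46, SE) and CG17377 (-6.74 ± 0.42, SE). Of 7 testis and sperm genes, 6 were lower, 6 also adjusted over the list alone (median -3.80, adjusted p = 6.28e-11). It also passed with an estimated correlation (adjusted p = 1.12e-07). Among its members exu was at -6.03 ± 0.38 (SE), Pglym87 at -3.80 ± 0.33 (SE), the dynein light chain gene Cdlc2 at -3.63 ± 0.29 (SE) and Tektin-A at -3.62 ± 0.35 (SE). Acp36DE, of the accessory gland, stood at 3.94 ± 0.51 (SD, n = 4) in wild-type and 4.33 ± 1.19 (SD, n = 4) in tudor males. Higher in tudor males were CG7252 (2.65 ± 0.47, SE), the photoreceptor gene Cpn (2.25 ± 0.26, SE), the endocytic receptor gene Cubn (2.10 ± 0.65, SE), ebony e (2.06 ± 0.36, SE) and the globin gene glob1 (1.98 ± 0.52, SE). Without the adult male 0-24 h replicate 2 array Cubn stood at 1.79, and without the tudor male 0-24 h replicate 2 array glob1 stood at 1.75, neither past the test. Cubn did not pass without a slide set term (1.50, adjusted p = 0.142) or in slide set B alone (adjusted p = 0.0936) either, and with the tudor arrays of 5 d alone neither gene passed. For e, 2 of the 4 tudor arrays lay above the wild-type mean. Its value was 0.64 and did not pass with the arrays of 5 d alone. By limma, 1589 of 7003 probes passed, 734 higher and 855 lower. Of these, 269 and 652 differed at least 2-fold. Slide set B alone gave 1194 probes, ages of 0 to 24 h alone 897 and 5 d alone 916.

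**Figure D3:**
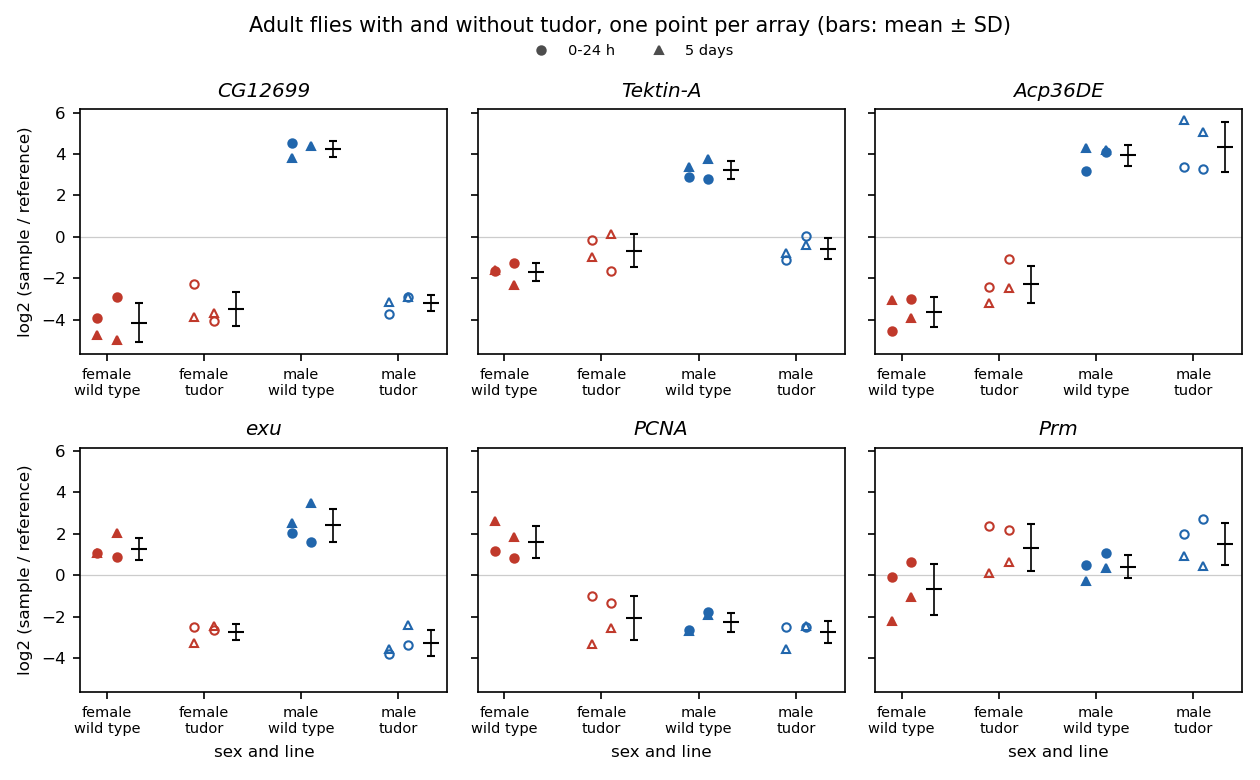
Log2 ratio of sample to reference (y axis) of CG12699, Tektin-A, Acp36DE, exu, PCNA and Prm in wild-type and tudor adults of each sex (x axis), with 1 point per array, circles for 0 to 24 h and triangles for 5 d, filled for wild type and open for tudor, and bars for the mean ± SD of the arrays. The genes were picked for the picture after their values had been seen. CG12699 stands at 4.24 ± 0.40 (SD, n = 3) in wild-type and -3.17 ± 0.39 (SD, n = 4) in tudor males.

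The tudor effect itself differed between the sexes in 1510 of 7003 probes, 549 with a higher and 961 with a lower value in males than in females. For CG10252 the effect was -7.60 ± 0.36 (SE) in males and 1.02 ± 0.36 (SE) in females. They differed by -8.62 ± 0.49 (SE; adjusted p = 5.53e-13). The differences were -8.41 ± 0.62 (SE) for CG8701, -8.22 ± 0.51 (SE) for CG12699, -7.86 ± 0.47 (SE) for CG1324 and -7.17 ± 0.52 (SE) for CG17349. Of 7 testis and sperm genes, 6 had a lower effect in males and 1 a higher effect, 6 and 1 also adjusted over the list alone (median -4.34, adjusted p = 5.04e-06). The effect on mtrm was -3.74 ± 0.67 (SE) in females and 0.38 ± 0.63 (SE) in males. They differed by 4.12 ± 0.90 (SE; adjusted p = 0.00112). The differences were 3.89 ± 0.75 (SE) for Pxt, 3.41 ± 0.45 (SE) for the peptide transporter gene yin, 3.41 ± 0.72 (SE) for CG5568 and 3.19 ± 0.59 (SE) for PCNA. Of 16 cell cycle and DNA replication genes, 6 had a higher effect in males, 8 adjusted over the list alone (median 0.84, adjusted p = 0.0246). The list call ended with an estimated correlation (adjusted p = 0.628), with quantile normalization (adjusted p = 0.151) and with complete probes only (adjusted p = 0.0591). Leaving out centring moved the median of all probes by 0.16, and quantile normalization, which moved it by 0.23, gave 563 higher and 648 lower. Slide set B alone gave 1087 probes, where Pxt was not called (2.42, adjusted p = 0.06), and the arrays of 0 to 24 h alone 525, where mtrm, Pxt and CG5568 were not called and the cell cycle list did not pass (median 0.41, adjusted p = 0.149).

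With age from 0 to 24 h to 30 d, transcripts of Scp1 in wild-type females fell by 2.56 ± 0.27 (SE) per 10 days, from a mean of 4.16 at 0 to 24 h to -3.33 at 30 d (adjusted p = 3.1e-07). The cuticle protein gene Cpr49Ae fell by 1.74 ± 0.37 (SE) per 10 days, as did Prp4k (-1.27 ± 0.32, SE), CG8560 (-1.13 ± 0.17, SE) and CG2691 (-1.11 ± 0.22, SE). The serpin gene Spn88Eb rose by 0.81 ± 0.14 (SE) per 10 days, CG4757 by 0.76 ± 0.14 (SE), Arc1, which encodes a Gag-like protein of neurons, by 0.74 ± 0.16 (SE), CG2233 by 0.68 ± 0.11 (SE) and CG16926 by 0.62 ± 0.12 (SE). Of 16 muscle structure genes, 6 fell, 8 adjusted over the list alone (median -0.34, adjusted p = 3.87e-05), with Zasp66 at -0.73 ± 0.12 (SE) and Obsc at -0.69 ± 0.13 (SE). The muscle list did not pass with an estimated correlation (adjusted p = 0.132), and its median was -0.21 without adult female 0-24 h replicate 2 and -0.12 without the arrays of 0 to 24 h. Of 18 neuronal genes, 5 fell, 6 adjusted over the list alone (median -0.22, adjusted p = 0.00166), with slo at -0.60 ± 0.13 (SE) and nrv2 at -0.52 ± 0.09 (SE). The neuronal list did not pass with an estimated correlation either (adjusted p = 0.132), and its median was -0.11 without a slide set term. Of 16 cell cycle and DNA replication genes, 3 rose, 6 adjusted over the list alone (median 0.22, adjusted p = 3.87e-05), with cyclin E gene CycE at 0.57 ± 0.10 (SE), and this list call was lost as well with an estimated correlation (adjusted p = 0.132). By limma, 597 of 6860 probes passed, 264 higher and 333 lower with age. Without a slide set term the count was 1214, and CG16926 was not called (0.41, adjusted p = 0.0569). It was 325 without centring. The count was 88 without the arrays of 0 to 24 h, where slo (-0.54) and Cpr49Ae (-0.92) were not called, and 280 in slide set B alone, while slide set A held no ages past 15 d. With log2 of age CG8560 was not called (adjusted p = 0.0753). The count was 161 without adult female 0-24 h replicate 2, where Cpr49Ae (-1.32) and Prp4k (-0.99) were not called, 334 without adult female 0-24 h replicate 1 and 396 without adult female 30 d replicate 1.

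In ageing males, Arc1 rose by 1.06 ± 0.16 (SE) per 10 days, from a mean of -0.67 at 0 to 24 h to 4.17 at 30 d (adjusted p = 4.19e-05). Spn88Eb rose by 0.97 ± 0.13 (SE), CG4757 by 0.93 ± 0.13 (SE), the stomatin-like Mec2 by 0.92 ± 0.11 (SE) and CG4377 by 0.81 ± 0.18 (SE) per 10 days. Without a slide set term CG4377 stood at 0.47 and was not called (adjusted p = 0.176). Scp1 fell by 2.41 ± 0.27 (SE; adjusted p = 4.53e-07), as did Cpr49Ae (-1.65 ± 0.37, SE), fln (-1.55 ± 0.51, SE), the chitin-binding gene obst-A (-1.09 ± 0.28, SE) and Prp4k (-1.05 ± 0.27, SE) per 10 days. Of 16 muscle structure genes, 6 fell, 8 adjusted over the list alone (median -0.26, adjusted p = 0.00428), with Actn at -0.67 ± 0.13 (SE), and the call was lost with an estimated correlation (adjusted p = 0.239). Without a slide set term the list (adjusted p = 0.0851) and Actn (adjusted p = 0.0574) did not pass. Of 8 genes of mitochondrial respiration, 5 fell, 5 also adjusted over the list alone (median -0.33, adjusted p = 0.00428), with the ATP synthase subunit gene ATPsynO at -0.68 ± 0.14 (SE). This call was lost (adjusted p = 0.12 with an estimated correlation), also with complete probes only (adjusted p = 0.0914). Of 9 proteasome genes, 1 fell, 5 adjusted over the list alone (median -0.20, adjusted p = 0.00428). It did not hold (adjusted p = 0.213 with an estimated correlation), nor with complete probes only (adjusted p = 0.0957), and its median was -0.13 without adult male 0-24 h replicate 2. Of 8 antimicrobial and immune genes, 2 rose, 2 also adjusted over the list alone (median 0.10, adjusted p = 0.0162), the immune-regulated catalase gene Irc (0.64 ± 0.11, SE) and Relish Rel (0.48 ± 0.10, SE). The immune call was lost with an estimated correlation (adjusted p = 0.12), without adult male 0-24 h replicate 2 (adjusted p = 0.0517, median 0.19), without a slide set term (adjusted p = 0.14) and with complete probes only (adjusted p = 0.245). Over both sexes, 59 probes rose and 69 fell with age in each, against 13.4 and 19.2 for independent lists of these sizes. The lists are not independent, because both slopes come from 1 fit with a shared slide set term. The sexes also shared slides at all 8 ages, where deviations of arrays on the same slide correlated at -0.0295 to 0.552, so part of the excess may be technical. By limma, 744 of 6860 probes passed in males, 349 higher and 395 lower, with 362 and 150 without centring and 358 and 255 with quantile normalization. The count was 361 without the arrays of 0 to 24 h and 404 in slide set B alone. In both fln and obst-A were not called, nor was fln without centring (adjusted p = 0.0567). The immune and proteasome lists did not pass without the arrays of 0 to 24 h (adjusted p = 0.259 and 0.1). Without adult male 0-24 h replicate 2 the count was 450. There fln (-1.01), obst-A (-0.93) and Prp4k (-0.82) were not called.

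The slope with age differed between the sexes in 94 of 6860 probes, 38 higher and 56 lower in males. CG10096 changed by -0.84 ± 0.14 (SE) per 10 days in females and 0.04 ± 0.14 (SE) in males, a difference of 0.88 ± 0.19 (SE; adjusted p = 0.0234). The difference was 0.82 ± 0.18 (SE) for CG8329, 0.79 ± 0.17 (SE) for CG30281, 0.71 ± 0.16 (SE) for Ag5r and 0.58 ± 0.15 (SE) for Mec2. CG8701 had the lowest difference (-0.91 ± 0.20, SE), followed by the spermatid gene soti (-0.74 ± 0.15, SE), Hsp27 (-0.68 ± 0.13, SE), tio (-0.66 ± 0.16, SE) and CycE (-0.66 ± 0.14, SE). Of 16 cell cycle and DNA replication genes 1 had a lower slope in males, 1 also adjusted over the list alone (median -0.27, adjusted p = 0.00332). The cell cycle list did not pass with an estimated correlation (adjusted p = 0.219), and its median was -0.17 without adult female 0-24 h replicate 2. Of 7 testis and sperm genes the count was 0, and 0 adjusted over the list alone (median -0.30, adjusted p = 0.0218), a call lost with an estimated correlation (adjusted p = 0.105). Of 9 proteasome genes it was 0, with 1 adjusted over the list alone (median -0.22, adjusted p = 0.0218), a call lost in the same way (adjusted p = 0.36 with an estimated correlation). At limma's unadjusted p under 0.05, 2 testis genes and 4 proteasome genes had a lower slope in males and 0 a higher one. By limma, 6 probes were higher and 3 lower without centring, 102 and 94 with quantile normalization, and 3 in all passed in slide set B alone, where none of the 10 genes named here was called. Without centring Ag5r, Mec2, soti, tio and CycE were not called, and without the arrays of 0 to 24 h CG10096, CG8329, Ag5r, Mec2 and Hsp27 were not. The count was 24 and 46 without adult female 0-24 h replicate 1 and 2. It was 30 without adult female 30 d replicate 1, 47 without adult male 25 d replicate 1, and 48 and 58 without adult male 30 d replicate 1 and 2. The calls of CG8329 (0.76), CG30281 (0.72), Ag5r (0.63) and CG8701 (-0.82) ended without adult female 30 d replicate 1, as did that of the proteasome list (adjusted p = 0.0927). Those of Mec2 (0.49) and tio (-0.60) ended without adult male 30 d replicate 2, and that of the testis list without adult female 30 d replicate 2 (adjusted p = 0.0532). Without a slide set term, where 15 probes passed, CG8329, CG30281, Ag5r, Mec2, tio and CycE were not called (adjusted p from 0.0614 for tio to 0.225 for Mec2). With quantile normalization the testis and proteasome lists did not pass (adjusted p = 0.0576 and 0.272), nor did the testis list in slide set B alone (adjusted p = 0.204).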

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

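The tests of the shifted probe rows and of a wrong label for 4 arrays, and the tests of the slide set and of a shared offset for the 9 pupal arrays, were chosen only after the result had been seen, as were the embryo benchmark for the offset and the fit of tudor to its own 2 ages. So were the fit of tudor at 0 to 24 h alone and the counts of list members in tudor males. All others in this part were fixed before. Among array medians, embryo 22-23 h replicate 1 lay at 0.146, apart from the nearest of its window at -0.032, by a rule that marks about 1 in 20 groups by chance. The rule was run on several measures over many sets of arrays, so some mark was likely by chance.

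The effect of tudor differed between the sexes by a direct test in 1510 probes. The testis and sperm list differed by a median of -4.34, with hmw at -4.92, Tektin-A at -4.82, Pglym87 at -4.34 and Cdlc2 at -4.22. Outside the list, CG10252 stood at -8.62, CG8701 at -8.41, CG12699 at -8.22, CG1324 at -7.86 and CG17349 at -7.17. The cell cycle and DNA replication list differed by a median of 0.84, with PCNA at 3.19, Mcm6 at 2.52, aurB at 1.42 and Bub1 at 1.23. This list did not pass with an estimated correlation (adjusted p = 0.628). In slide set B alone Mcm6 (2.01), aurB (1.03), Bub1 (1.17) and, outside the list, Pxt (2.42) were not called. At 0 to 24 h alone the list (median 0.41, adjusted p = 0.149), Mcm6, aurB, Bub1, mtrm, Pxt and CG5568 were not called. In all arrays mtrm stood at 4.12, Pxt at 3.89, yin at 3.41 and CG5568 at 3.41. The slope with age differed between the sexes in 94 probes, with list medians of -0.27 for the cell cycle, -0.30 for testis and sperm and -0.22 for the proteasome, none past the test with an estimated correlation (adjusted p = 0.219, 0.105 and 0.36). Single genes stood at 0.88 for CG10096, 0.82 for CG8329, 0.79 for CG30281, 0.71 for Ag5r, 0.58 for Mec2, -0.91 for CG8701, -0.74 for soti, -0.68 for Hsp27, -0.66 for tio and -0.66 for CycE.

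Embryo 2-3 h replicate 1, embryo 4-5 h replicate 1, metamorphosis 12 h replicate 1 and metamorphosis 16 h replicate 1 resembled no array outside these 4 at the same probe rows. Likeness among the 4 was not tested. The 2 metamorphosis arrays correlated at 0.293 and 0.316 with means of neighbours that hold the other of the 2. With single arrays of other groups outside the 4 they reached at most 0.0478 and 0.0452. Against a single wrong label, the highest correlation at the same rows with an array of another group outside the 4 was 0.344. Part of their values may lie on other probe rows of the deposited table: at a shift of 120 rows, at least 8 stretches of 40 probes in each of the 4 correlated above 0.8 with neighbours in time, against at most 1 in any other array. Each of the 4 had 8 to 16 such stretches, with 209 to 218 stretches compared at the same rows. The shift thus covers a small part of each array, and the rest is not explained by it. No biological explanation was tested.

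At 20 to 80 h of metamorphosis the 9 replicate 1 arrays resembled their partners less (correlation from 0.308 to 0.488) than neighbours in time within their own set. The slide set alone would lower the embryo pairs too, which correlated at a median of 0.872 across the sets. An offset in staging of the whole set is argued against by a median offset of 0 h to the best match, though single offsets ran from -18 to 12 h and the best matches reached at most 0.488, and shifted rows by 0 stretches at the shift. An offset per probe shared by the 9 arrays may be the source: their differences from replicate 2 correlated with each other at a median of 0.627, against 0.351 in the embryo. It cannot be told apart from other causes, because changes over time within the sets, with probe means taken off, correlated at 0.318, under the lowest of 15 embryo pairs at 0.450, which a smaller change over time could also give, and no biological explanation was tested.

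Muscle, cuticle, phototransduction and detoxification lists were higher in tudor females, the last lost with an estimated correlation (adjusted p = 0.0739) and with complete probes only (adjusted p = 0.052). The centring of arrays done here is argued against as the source, as the lowest of the 4 list medians was still 0.43 without it. Any centring before deposit is unknown, so this test does not reach it. The pattern is consistent with a loss of ovary RNA from the pool: over the 6 ages without tudor flies, the 1673 measured probes higher in tudor females had a median of 0.77 for males over females, with 1266 past the test, against 0.07 for all probes. Arrays of those ages enter the tudor fit through the slide set and the variance, and with tudor fitted to its own 2 ages the median was 0.78 over 1362 probes. Tudor males have no ovary. At limma's unadjusted p under 0.05, 8 of 16 muscle, 7 of 12 cuticle and 6 of 9 phototransduction genes were higher there and 0 lower. Over all probes of that comparison, 2440 of 7003 had such a p in either direction. The muscle list did not pass as a list in tudor males. Of 40 detoxification genes, 3 were higher and 5 lower in tudor males. Loss of ovary RNA cannot account for the higher values in males. By the same unadjusted measure, 6 of 7 testis and sperm genes were lower in tudor males and 0 higher. A loss of testis RNA from the pool of males was not tested. A direct change in body tissues was not tested either, and both stay open.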

How the results depend on the processing

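The alternatives with each age of tudor alone, with tudor fitted to its own 2 ages, without the 9 pupal arrays, without the 4 arrays that resembled no other, without the last larval time point, without the 42 h replicate 1 array, with Sod3 left out of the muscle list and with values at the upper limit kept were chosen after the data had been seen. Of 302 gene results, 199 stayed on the same side of the threshold with the same sign under every alternative run, and 3 turned in sign. Of 45 list results, 16 stayed and 0 turned. With an estimated correlation 17 of the 45 passed, and 19 of all 240 list tests did. PPO1 turned to 0.049 per doubling of age in ageing males (adjusted p = 0.838), Hsp60B to 0.042 in the difference of slopes with probes averaged (adjusted p = 0.958) and CG7906 to -0.086 in larvae of slide set A (adjusted p = 0.95). Where a count moved by over 1.5 times, fewer probes or arrays account for part of it by construction, and otherwise the cause was not tested.

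With only probes measured on every array, the counts were 729 over the life cycle, 2177 in the embryo, 693 in metamorphosis, 1.6e+02 between larval sexes (156 higher and 3 lower in males), 1329 in the pupa and 3102 between adult sexes. They were 1617, 995 and 937 for tudor females, tudor males and their difference. Slide set A alone gave 0 by limma in the early embryo (1379 at an unadjusted p under 0.05), 3066 in the late embryo and 70 in the larva. Slide set B alone gave 146 between larval sexes, 600 in the prepupa and 450 in the pupa. It gave 280, 404 and 3 for ageing females, males and their difference. Means of every time point gave 3127 in the larva and 1278 in the pupa. The slide as a random block gave 447 between larval sexes. Tudor at 0 to 24 h alone gave 1229 in females, 897 in males and 525 for the difference, and at 5 d alone 916 in males. Fitted to its own 2 ages, tudor gave 2213 in females, 1205 in males and 1371 for the difference. Without the 9 pupal arrays, 481 probes passed over metamorphosis and 715 in the pupa. Without centring, 325 passed in ageing females and 9 for the difference of slopes. Without a slide set term these were 1214 and 15, and without flies of 0 to 24 h they were 88 and 19, with 361 in males. The difference of slopes gave 196 with quantile normalization and 160 with log2 of age.

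The replicate number as a block in place of the slide set gave 1511, 1194 and 38 probes for ageing females, ageing males and their difference, and moved no other count by over 1.5 times. With it the heat shock list ended between adult sexes (adjusted p = 0.0735), and the heat shock (adjusted p = 0.0711), fat body (adjusted p = 0.0814) and immune lists (adjusted p = 0.0557) in tudor females. In ageing males the muscle (adjusted p = 0.0978) and immune lists (adjusted p = 0.159) ended. Of the 302 gene results, 11 lost their call with this block and 2 gained one. The numbers do not pair the samples by the rule that every pair of groups should correlate above 0.1, met only by the 1 pair of sexed larval groups, at 0.72. Among late pupal groups 10 of 15 pairs did. Between adult sexes of the same age, arrays with the same number correlated at 0.273 to 0.552 at the 6 ages where they lay on the same 1 or 2 slides. At 25 d and 30 d the shared slides crossed the numbers, and arrays on the same slide correlated at 0.344 and -0.0295. The slide as a random block moved only the count between larval sexes by over 1.5 times.

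Without Sod3, the muscle list passed in its 6 comparisons, with medians of 3.05 in the late embryo, -2.28 in the prepupa, 2.91 in the late pupa, 1.25 in tudor females, and -0.40 and -0.28 in ageing females and males.

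With each array left out in turn, counts ranged from 6654 to 6732 over the life cycle (100 arrays drawn), 5447 to 6233 in the embryo and 968 to 1855 in metamorphosis. They ranged from 3366 to 4464 in the early embryo, 4666 to 5307 in the late embryo and 1580 to 2437 in the larva. Further ranges were 196 to 251 between larval sexes, 1791 to 2624 in the prepupa, 1632 to 2175 in the pupa, 1986 to 2293 in the late pupa and 4990 to 5112 between adult sexes. For tudor they ranged from 1900 to 2595 in females, 1200 to 1469 in males and 1283 to 1628 for the difference. For ageing they ranged from 161 to 832 in females, 450 to 760 in males and 24 to 122 for the difference. Signal over background was not used here, so what dim spots add to the spread could not be assessed. A lone array left in a group was assumed to vary like the other groups. Slide set B alone was not run for the 3 tests over many groups, where most groups hold 1 such array, nor were fits without disagreeing labels where a comparison has no such array.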

Other observations

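All tests in this part were fixed before their results were seen, while the gene groups given first were picked after their values had been seen. Some lists held called members but did not pass as lists. Between 0 to 2 h and 4 to 6.5 h of the embryo, 6 of 12 maternal and germ plasm genes fell and 1 rose (median -0.57), with 7 and 1 adjusted over the list alone, and the list did not pass (limma's cameraPR, adjusted p = 0.112). Of 20 neuronal genes in that comparison, 9 rose and 1 fell (median 0.58), with 10 and 1 adjusted over the list alone, and the list did not pass either (adjusted p = 0.112). Between adult sexes, where 5073 of 6860 probes passed, all 3 ribosomal protein genes were lower in males, 3 also adjusted over the list alone (median -0.73, adjusted p = 0.223 for the list). Of 8 antimicrobial and immune genes, 6 were higher in males and 1 lower, 6 and 1 also adjusted over the list alone (median 0.58, adjusted p = 0.899 for the list).

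Probes higher in male than in female larvae of the last time point may be transcripts of the testis germline. If so, they should be lower in adult tudor males, and of the 234 that could be tested 221 were, with a median tudor effect of -3.44 against 0.14 for all probes. In wild-type adults, 227 of 233 were higher in males. A single odd array is argued against as their source, since the lowest count of higher probes with 1 of the 4 sexed arrays left out was 183, against 236.

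Probes lower in tudor females may include maternal transcripts that the egg carries. These 950 probes stood at a median of 1.18 in embryos of 0 to 2 h, against -0.08 for all probes and -1.30 for probes higher in tudor females. Between 0 to 2 h and 4 to 6.5 h, 332 of the 928 probes lower in tudor females that could be tested fell and 148 rose. Their median change of -0.29, against 0.19 for all probes, lay between the bounds set for and against the hypothesis. The value lay close to the bound for it and was read from centred arrays. Leaving out centring moved the median of all probes in this comparison by -0.17, and these probes were not tested without it. The bounds concern this fall and not the level at 0 to 2 h, and by this test the hypothesis stays open.

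In each of the 13 comparisons with at least 3 arrays a side, counts were set against other splits of the same arrays. A split that mixes the real groups or ages adds their difference to the spread, which lowers its count. The splits therefore do not measure false calls under the real grouping, and no verdict on chance is drawn from them. Some other splits gave calls too, 18 in tudor females and 14 in tudor males, out of 34 with the real one, and 31 for the difference of the tudor effects, out of 100 with the real one. No other split gave as many probes as the real one: the real split was the 1 of 100 drawn, or of 34 for tudor females and tudor males. The highest other split gave 1941 probes against 3698 in the early embryo, 0 by limma against 4886 in the late embryo, 985 against 2063 in the larva, 65 against 2241 in the prepupa, 697 against 2050 in the pupa and 931 against 2333 in the late pupa. It gave 3561 against 5073 between adult sexes, 930 against 2645 in tudor females, 270 against 1589 in tudor males and 1417 against 1510 for their difference. It gave 5 against 597 in ageing females, 51 against 744 in ageing males and 1 against 94 for their difference.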
